A study of Mus musculus with 6 samples.

How the data were processed

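RNA from the kidney cortex of male mice was measured on 6 one-colour Agilent arrays, 3 from wild-type (WT) mice and 3 from mice lacking the C3a receptor (C3aR-/-), all labelled as controls. Per the labels, the control arm of the study started at 8 weeks of age on a chow with 10% of its calories from fat and received vehicle in place of streptozotocin, and the mice were killed 20 weeks after induction. Diabetic mice of the study were not analysed here. Per the labels' protocols, Cy3-labelled cRNA was made from 0.2 µg of RNA per sample. The groups and replicate numbers came from the sample titles. The labels do not say in words that each sample was a separate animal, so the p-values measure the spread between these samples.

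Per the file headers, the scanner images were read by Agilent Feature Extraction 10.7.1.1, which gave each spot an intensity with its background subtracted (the processed signal), a mean intensity, a local background intensity and flags. A table of log2 values for the same arrays was also deposited. The columns of that deposited log2 table had the same sorted values to within 0.000903 and the same median of 5.38, and correlated with the log2 processed signal of their own array at 0.995 to 0.996, so its scale was taken as log2. Equal sorted values are what quantile normalisation gives, so that table is not independent of the quantile setting below. How the authors otherwise centred and filtered that table is not given in the sources used here. It served as an alternative only. Coordinates are those of the array files, on mouse build mm9. Gene symbols came from a RefSeq table of assembly GRCm38.p6, used for names only, which matched 32994 of 56605 distinct probes. A further 23230 probes kept the name in the array files and 381 had no name. The match changed the symbol of 1535 probes.

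Each array held 59305 transcript spots, of which 33530 to 35147 (56.5% to 59.3%) were well above background. No spot was saturated. The number of arrays limits the precision of each comparison. Probes spotted 10 times on each array had a median SD between spots of 0.033 to 0.054 on the log2 scale. The processed signal was put on the log2 scale and each array's 75th percentile over transcript spots was subtracted (662 to 827 before the log). Control spots and spots flagged as outliers were left out, and spots of one probe were averaged. This left out 106 probes for which an array had no unflagged spot. Probes were kept when well above background on all 3 arrays of at least 1 genotype, which gave 30867 probes, and the brightest probe stood for each of 20490 genes. Where a called gene is named, its other probes are named with it when they had the opposite sign or a log2 change under 0.1 in size.

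The genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every adjusted p of a gene below is from limma. For a probe not well above background on any array of one genotype, a bound replaced the fold change. It sets the brighter genotype's mean against the dimmer genotype's mean of, per array, the higher of the probe's own value and the lowest value of any probe well above background. That lowest value is the floor of the array. The limit of a single probe can lie higher, so a fold given as "at least" is a bound by this rule and not a strict one. On C3aR-/- replicate 3, Klrb1c at -5.10 was not well above background although the floor was -5.43. Sets of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists with at least 5 tested genes out of 32 lists. A camera p compares the genes of a list with all other genes. Calls near C3ar1 were compared with calls elsewhere by Fisher's exact test, two-sided.

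On simulated arrays with the means and spreads of the 20490 genes of this comparison and 200 changed genes, the fit recovered 40.4% of log2 changes of 0.5, 71.2% of 1, 91.8% of 2 and 98.0% of 3, and 5.40% of its calls were false. A simulation without changes called 1 gene and 0 lists. A list shifted by 0.5 was recovered. The simulated genes were drawn independently of each other, so these results leave open how often lists of correlated genes are called falsely. With 200 changed genes against 2931 called in the real data, the recovery there may differ. No slide effect was simulated, so the 5.40% does not cover calls caused by the slide.

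The 32 lists of pathways and cell type markers, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, of the genes with an adjusted p under 0.05 and no overlap between genotypes, the 10 largest rises and 10 largest falls with a symbol of a known gene. It left out predicted genes, clones, accessions, long intergenic RNAs and array identifiers. It also took C3ar1, up to 4 members of each list by smallest p, and up to 10 called genes within 10 Mb of C3ar1 by smallest p. Some genes that the rule took are not reported here by name, and the counts over all genes and over the lists include them. The immunoglobulin transcripts were grouped only after the values were seen, as the 60 tested genes whose description in the array files names an immunoglobulin kappa, lambda or heavy chain. Rbpj, whose description names a protein that binds such a gene, was left out.

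All 3 WT arrays lay on one slide and in one scan, and all 3 C3aR-/- arrays on another, so slide and genotype could not be told apart and no slide term could be fitted. The alternatives were normexp background correction with an offset of 50, quantile normalisation, median scaling, the deposited log2 table, 2 other filters on dim probes, other rules for several probes of a gene, other variance models, array weights, a replicate block, and leaving out each array. For the lists they also included an estimated correlation and limma's fry, and for the region around C3ar1 other windows and a rank test.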

Results

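The series measured gene expression in the kidney cortex of male C57BL/6 mice with and without C3ar1, the gene for the receptor of the complement fragment C3a. Only the control arm is represented, with 3 WT and 3 C3aR-/- arrays, so the comparison asks what the loss of the receptor changed in mice without induced diabetes. Levels are given as log2 signal relative to the array's 75th percentile, as mean ± SD over 3 arrays.

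C3ar1 itself could not be followed. Its single probe (mm9, chromosome 6, 122798222 to 122798281) was well above background on 1 of the 6 arrays, WT replicate 1. The level was -5.60 ± 0.57 (n = 3) in WT and -5.71 ± 0.30 (n = 3) in C3aR-/- cortex, a difference of -0.11 that was smaller than the spread between arrays (exact permutation test, two-sided, p = 0.9, where the smallest possible p was 0.1). With both genotypes near the floor, and with the deleted part of the gene not given in the sources used here, this probe gives no check of the genotype labels. The processed signal was 20.9, 9.19 and 14.1 in WT replicates 1 to 3 and 14.6, 18.6 and 11.1 in C3aR-/- replicates 1 to 3.

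The genotypes differed in many genes. Among 20490 genes, 1444 were higher and 1487 lower in C3aR-/- cortex at an adjusted p under 0.05, of which 116 were at least 2-fold higher and 237 at least 2-fold lower. The 2-fold counts were 26 and 97 with normexp background correction, and 51 and 166 with only probes well above background on all 6 arrays. The groups did not overlap in any of the 2931 called genes. Over all genes they did not overlap in 41.3%, where chance gives 10%. The median change of the called genes was 0.48 in absolute log2 units. The count was lower with any array left out, at 933, 849 and 1444 without WT replicates 1, 2 and 3 and at 1687, 1167 and 727 without C3aR-/- replicates 1, 2 and 3. C3aR-/- replicate 1 stood apart from the other arrays of its genotype, with 145 non-uniform spots against 2 to 8 on every other array and a value of 30.2 on the second principal component against -20.0 and -18.7. Without it, 655 genes were higher and 1032 lower, 85 and 258 of them by at least 2-fold, and 9 gene lists were called in place of 8. Slide and genotype coincided, so every difference between the genotypes is also a difference between slides.

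Among the 10 largest rises, Igfbp1, a secreted binding protein of insulin-like growth factors that is induced by fasting in liver, rose 7.82-fold (log2 change 2.97, SE 0.27, adjusted p = 0.00519; mm9, chromosome 11, 7102442 to 7102501). Depp1, a target of FOXO transcription factors, rose 7.56-fold (log2 change 2.92, SE 0.25, adjusted p = 0.00437). Grem1, an antagonist of bone morphogenetic proteins, was well above background on 1 of 3 WT arrays and was at least 5.89-fold higher with the other 2 at the floor (fitted log2 change 3.31, SE 0.56, adjusted p = 0.0208). Cyp27b1, the gene of the enzyme that makes active vitamin D, rose 4.22-fold (adjusted p = 0.0101), and Bbox1, the last enzyme of carnitine synthesis, 3.50-fold (adjusted p = 0.00919). Nr1d1, the clock repressor REV-ERB alpha, rose 4.44-fold (adjusted p = 0.0242). Cthrc1, Ifna5 and Atp12a were not well above background on any WT array and were at least 1.70-fold, 1.43-fold and 1.08-fold higher.

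Among the 10 largest falls, Jchain, which joins the units of IgA and IgM, was 6.30-fold lower in C3aR-/- cortex (log2 change -2.65, SE 0.20, adjusted p = 0.0034; mm9, chromosome 5, 88949919 to 88949978), and Igh-VJ558, an immunoglobulin heavy chain entry, was 5.34-fold lower (adjusted p = 0.00182). Tfrc, the transferrin receptor, was 4.23-fold lower (log2 change -2.08, SE 0.19, adjusted p = 0.00543), with its other probe at -1.78. Mfsd2a, a transporter of lysophospholipids, was 4.67-fold lower (adjusted p = 0.0109) and the pseudogene Ptma-ps2 4.54-fold lower (adjusted p = 0.00156). Thbs4, Fam186b, the chemokine receptor gene Ccr6 and Hsd17b13 were not well above background on any C3aR-/- array and were at least 2.83-fold, 2.83-fold, 2.43-fold and 2.21-fold lower. Mir124-2hg was called at -2.75 (SE 0.68, adjusted p = 0.0478) with 1 C3aR-/- array well above background, and stood at -1.98 with the other 2 at the floor. Of the 19 rises and falls described here, 10 were still called without each array in turn. The other 9 were Grem1, Cthrc1, Nr1d1, Atp12a, Thbs4, Fam186b, Ccr6, Hsd17b13 and Mir124-2hg, with a highest adjusted p of 0.115, for Mir124-2hg.

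**Figure D1:**
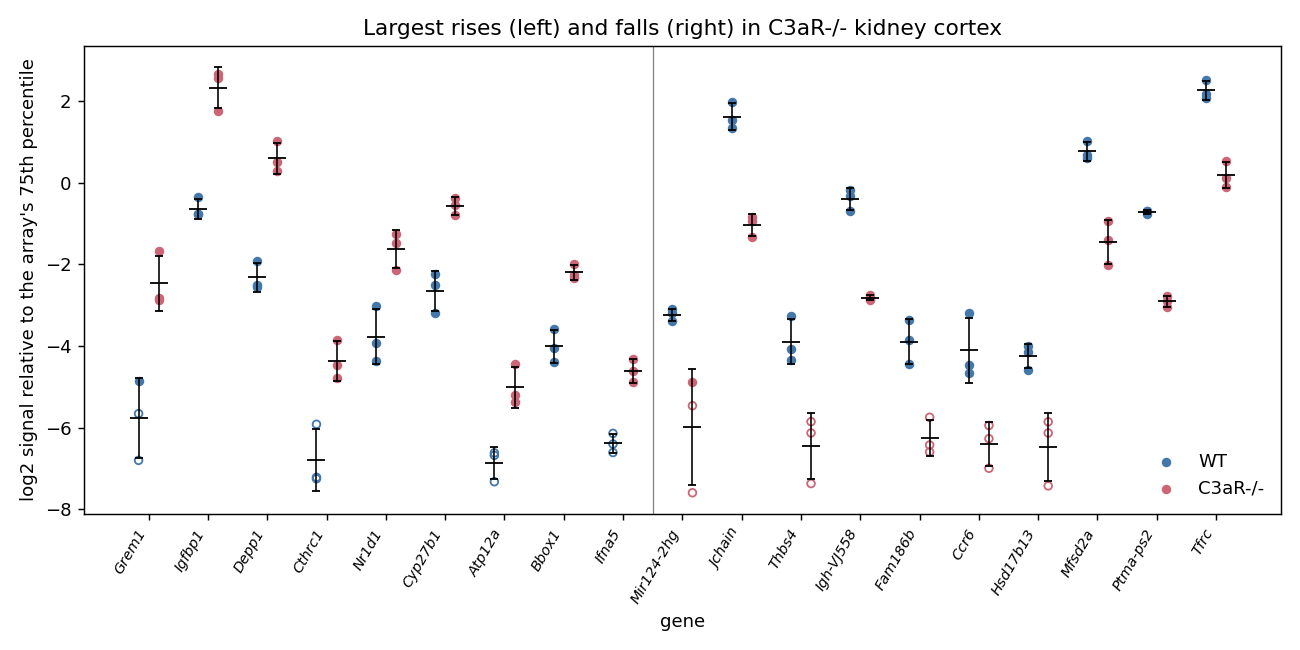
Log2 signal relative to the array's 75th percentile for 9 of the 10 largest rises and the 10 largest falls, with 1 point per array (WT blue, C3aR-/- red, open when not well above background) and bars for mean ± SD of 3 arrays. The genotypes do not overlap in any of these genes because the rule that named them required it. Open points fill every array of one genotype in 7 of the genes.

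Genes of fatty acid oxidation and PPAR-alpha targets were higher in C3aR-/- cortex. Of 29 measured, 13 rose, 0 fell and 16 did not pass, and 21 rose when adjusted over the list alone. All 29 had a positive log2 change, with a median of 0.42. Fabp1, a fatty acid binding protein, rose by 0.95 (SE 0.13, adjusted p = 0.012), the carnitine carrier Slc25a20 by 0.55 (SE 0.08), the thiolase Acaa2 by 0.42 (SE 0.06) and the acetyltransferase Crat by 0.35 (SE 0.06). The list had an adjusted p of 3.54e-08 (camera), and adjusted p = 0.793 with an estimated correlation. Angptl4, an inhibitor of lipoprotein lipase chosen after its values were seen, rose by 1.58 (SE 0.37, adjusted p = 0.0418). None of the 8 called lists was called with an estimated correlation, where the lowest adjusted p of any list was 0.793, and fry called 5 lists, 4 of the 8 and lipogenesis. Of 70 further called genes among the 4 members of each list with the smallest p, 13 were called without each array in turn, and the highest adjusted p among the others was 0.136, for Glo1.

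Cholesterol synthesis went the other way. Of 22 genes, 0 rose, 9 fell and 13 did not pass, with 10 lower and 2 higher when adjusted over the list alone, a median of -0.34 and an adjusted p of 0.00019 (camera; adjusted p = 0.793 with an estimated correlation and 0.0609 with fry, so neither called it). Msmo1 fell by 1.28 (SE 0.18, adjusted p = 0.0137), Idi1 by 0.88 (SE 0.12) and Lss by 0.68 (SE 0.11). Hsd17b7 counts among the 9 by its brightest probe, at -0.57 (SE 0.10). Its other probes were at -0.33 and 0.01, so no direction is given for that gene. Lipogenesis genes were not called as a list by camera (adjusted p = 0.128) but were by fry (adjusted p = 0.0322), and 5 of 18 fell and 0 rose (6 lower and 1 higher when adjusted over the list alone). Srebf1, the transcription factor that drives fatty acid synthesis, fell by 0.95 (SE 0.12, adjusted p = 0.0108), Acaca by 0.72 (SE 0.08) and Fasn by 0.56 (SE 0.08).

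Proximal tubule and energy genes were shifted upward. Of 23 proximal tubule markers 5 rose and 0 fell, with 6 higher when adjusted over the list alone and a median of 0.19 (camera, adjusted p = 0.00097; adjusted p = 0.793 with an estimated correlation). The neutral amino acid transporter Slc6a19 rose by 1.12 (SE 0.11, adjusted p = 0.00612), the lactate transporter Slc5a12 by 0.73 (SE 0.08) and Slc7a7 by 0.53 (SE 0.08). Of 35 oxidative phosphorylation genes 4 rose and 0 fell, with 6 higher when adjusted over the list alone and a median of 0.15 (camera, adjusted p = 0.000232; adjusted p = 0.793 with an estimated correlation). Those 4 were 11.4% of the list, under the 14.3% called over all genes. The 4 were genes of ATP synthase subunits, Atp5j, Atp5a1, Atp5o and Atp5b, with log2 changes of 0.34, 0.34, 0.27 and 0.23 and a second Atp5o probe at 0.07. Of 27 genes of glucose transport, glycolysis and gluconeogenesis 7 rose and 2 fell, with 16 higher and 3 lower when adjusted over the list alone (camera, adjusted p = 0.0281; adjusted p = 0.793 with an estimated correlation). The gluconeogenic enzyme gene Pck1 rose by 0.61 (SE 0.11, adjusted p = 0.023) and the glucose transporter Slc2a2 by 0.69 (SE 0.12), and Slc2a1 fell by 0.51 (SE 0.08). Under quantile normalisation the calls of the proximal tubule, oxidative phosphorylation and glucose lists were lost. The calls of the oxidative phosphorylation and glucose lists were also lost in the deposited log2 table, whose columns likewise shared one set of sorted values. The call of the glucose list was lost too with the mean of the gene's probes, and that of the oxidative phosphorylation list with fry (adjusted p = 0.0534).

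Markers of B cells and plasma cells were lower. Of 7 genes, 3 fell and 0 rose, with 4 lower when adjusted over the list alone, and all 7 had a negative log2 change with a median of -0.75 (camera, adjusted p = 0.00175; adjusted p = 0.793 with an estimated correlation). Besides Jchain, Mzb1 fell by 0.69 (SE 0.12, adjusted p = 0.0205) and Pou2af1 by 1.23 (SE 0.29, adjusted p = 0.0444; -1.12 with 1 dim C3aR-/- array at the floor), while Cd22 at -0.68 did not pass (adjusted p = 0.0618). Of the 60 immunoglobulin transcripts, grouped after the values were seen, 40 fell and 0 rose (limma; 47 lower and 0 higher at an unadjusted p under 0.05), with a median of -2.20, or -1.72 with the 13 transcripts not well above background on any C3aR-/- array at their bound. Their mean level was -2.78 ± 0.25 (n = 3) in WT and -4.70 ± 0.10 (n = 3) in C3aR-/- cortex. The 13 dim transcripts entered these means at their own values and not at the floor, which widens the gap. Transcripts dim on only some C3aR-/- arrays kept their own values in the median of -1.72 too, so it is only partly bounded. One of them, kappa variable 12-41, had a C3aR-/- mean of -6.58, below the lowest C3aR-/- floor of -5.47. The constant region of IgA fell by 2.68 (SE 0.16, adjusted p = 0.00182) and that of the kappa light chain by 2.53 (SE 0.17, adjusted p = 0.00233). Of 2 entries for the constant region of mu, one fell by 1.63 (adjusted p = 0.0368) and the other, at -0.48, did not pass (adjusted p = 0.287). Those of gamma 2B (-0.25), gamma 2C (-0.68), delta (-1.30), lambda 1 (-1.52) and lambda 3 (-0.97) did not pass either (adjusted p = 0.106 to 0.579). These transcripts share sequence, so their probes cannot be read as 60 independent genes. The number that fell was 25 without WT replicate 1, and 34 without C3aR-/- replicate 1. It was 12 with only probes well above background on all 6 arrays, a filter that also removes dim transcripts. Of 16 T cell and NK cell markers 0 passed in limma (1 lower and 0 higher at an unadjusted p under 0.05), with a median of -0.16 (camera, adjusted p = 0.22; fry, adjusted p = 0.607). Of 21 macrophage and dendritic cell markers only Cd68 passed, at -0.58 (SE 0.10, adjusted p = 0.023), with a list adjusted p of 0.096, although 18 of the 21 had a negative log2 change (5 lower and 1 higher at an unadjusted p under 0.05).

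**Figure D2:**
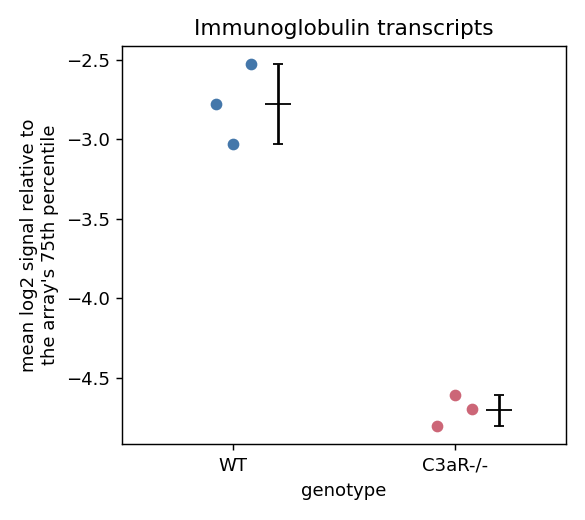
Mean log2 signal of 60 immunoglobulin transcripts relative to the array's 75th percentile, 1 point per array, with bars for mean ± SD of 3 arrays per genotype. The WT arrays lie between -3.03 and -2.53 and the C3aR-/- arrays between -4.80 and -4.61. Transcripts not well above background enter at their own values and not at the floor, which widens the gap.

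In the last 2 called lists few genes passed singly, 9.52% of each list against 14.3% of all genes. Of 21 genes of endoplasmic reticulum stress and ATF4 targets 2 rose, with 4 higher when adjusted over the list alone and a median of 0.41 (camera, adjusted p = 0.0175; adjusted p = 0.806 with an estimated correlation). The 2 were the serine synthesis enzymes Psat1 (0.60, SE 0.07, adjusted p = 0.00921) and Phgdh (0.68, SE 0.15, adjusted p = 0.0353). Of all 21 members, 17 had a positive and 4 a negative log2 change. Of 21 cell cycle genes 2 fell, Ccne1 (-0.61, SE 0.14, adjusted p = 0.037) and Mcm5 (-0.48, SE 0.11), with 2 lower when adjusted over the list alone (camera, adjusted p = 0.0402; adjusted p = 0.806 with an estimated correlation). Of these 21, 16 had a negative and 5 a positive log2 change, with a median of -0.37. The call of the cell cycle list was lost in 9 of 19 other settings. These were an estimated correlation, fry (adjusted p = 0.350), quantile normalisation, the deposited log2 table, no filter on dim probes, and leaving out WT replicate 1 or 2 or C3aR-/- replicate 1 or 3. The call of the stress list was lost with fry (adjusted p = 0.255) and without WT replicate 2, C3aR-/- replicate 2 or C3aR-/- replicate 3.

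**Figure D3:**
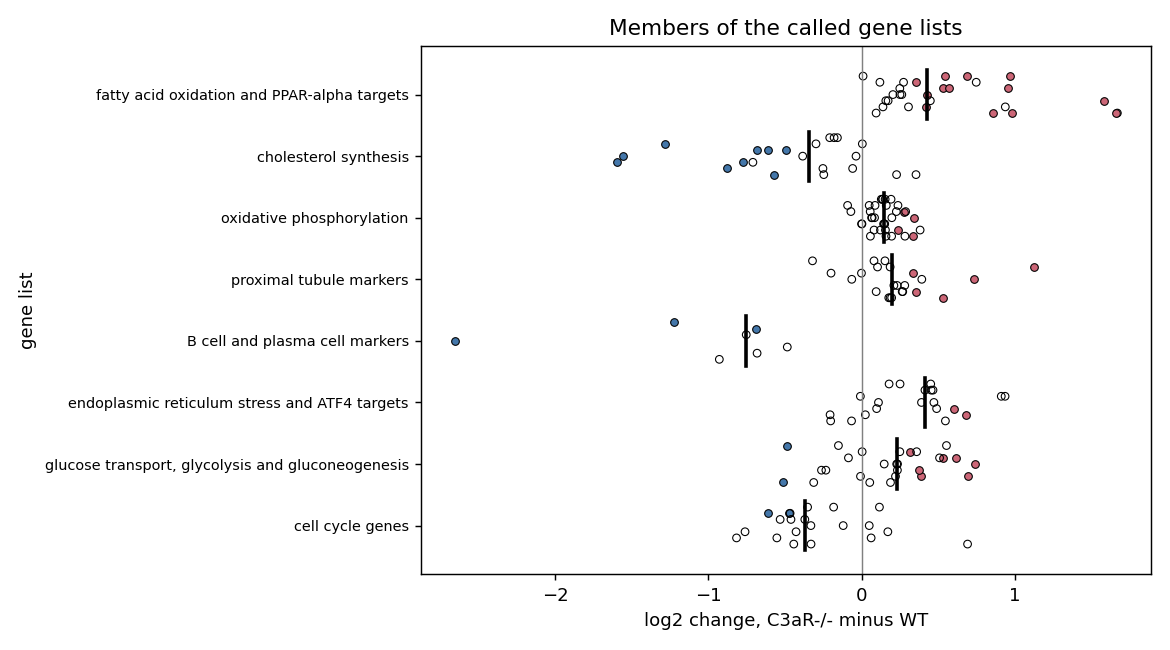
Log2 change (C3aR-/- minus WT) of each member of the 8 gene lists called by camera, filled when the gene passed at an adjusted p under 0.05 (red higher, blue lower), with a vertical bar at the list's median. The medians run from -0.75 for B cell and plasma cell markers to 0.42 for fatty acid oxidation.

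The complement system was not called as a list (adjusted p = 0.858), with 2 of 25 genes higher and 0 lower, and the same numbers when adjusted over the list alone. C3, whose fragment is the ligand of the deleted receptor, rose by 0.40 (SE 0.07, adjusted p = 0.0195), and Cfi, a protease that inactivates C3b, by 0.49 (SE 0.08, adjusted p = 0.0175). Inflammatory cytokine and NF-kB genes were not called either (adjusted p = 0.491). Tlr4, the receptor for bacterial lipopolysaccharide, was at -0.66 (SE 0.06, adjusted p = 0.0052) by its brightest probe, but another probe of the gene was at 0.05, so no direction is given for the gene. Nfkb2 rose by 0.46 (SE 0.08, adjusted p = 0.0244). Of 29 matrix and fibroblast genes (list adjusted p = 0.57) 2 rose, Lox by 0.84 (SE 0.12, adjusted p = 0.0148) and Col4a2 by 0.39 (SE 0.07), and of 17 tubular injury genes (list adjusted p = 0.096) Krt18 alone passed, at 0.50 (SE 0.07, adjusted p = 0.0115). Adjusted over the list alone, the counts of the macrophage, NF-kB, matrix and injury lists were the same.

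No excess of called genes around C3ar1 was detected. Within 10 Mb on chromosome 6, 31 of 257 tested genes (12.1%) were called, against 2884 of 20162 (14.3%) elsewhere (odds ratio 0.82, 95% interval 0.54 to 1.20, Fisher's exact test, p = 0.369). The called genes there included Depp1 and Clec2h, which rose by 1.12 (SE 0.09, adjusted p = 0.00437). Klrb1c and Klrk1, receptor genes of natural killer cells, fell by 0.91 and 0.44, and Clec9a, Tigar, Tuba3a and Parp11 fell by 0.73, 0.76, 0.66 and 0.52. Bid and Mtmr14 rose by 0.51 and 0.46, with a second Mtmr14 probe at 0.08. Of these 10 genes, 8 were called without each array in turn. The calls of Klrk1 and Bid were each lost when any 1 array but C3aR-/- replicate 1 was left out, with adjusted p values up to 0.0778 and 0.0730, and were lost in 8 and 7 of 17 other settings in all.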

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

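The immunoglobulin count was added after the data were seen, and every other alternative was planned. The count of changed genes, 2931 as reported, lay between 2327 and 4000 under 9 of 11 changes of processing. It was 936 without a filter on dim probes, where more genes were tested, and 650 with the replicate block. It lay between 727 and 1687 without 1 array, where fewer samples were fitted. Same-numbered arrays did not deviate together (correlations of 0.038, -0.028 and -0.071), so the block says nothing of the size of the effects. Of the called genes, 49.3% were higher in C3aR-/- cortex, and 63.4% (1820 higher, 1052 lower) under median scaling. The count of at least 2-fold changes, 353 as reported, was 123 (26 higher, 97 lower) with normexp, whose offset shrinks changes of dim probes. It was 217 (51 higher, 166 lower) with only probes well above background on all 6 arrays, and it lay between 245 and 343 without 1 array. Against 8 lists as reported, 4 were called under quantile normalisation (4 of the 8), 13 without a filter (7 of the 8), 5 with fry (4 of the 8) and 0 with an estimated correlation. Without 1 array, between 6 and 11 were called. The cause of the first 2 was not tested, and no called list changed the sign of its mean in any setting. The C3ar1 difference moved by less than the spread between arrays, between -0.39 and 0.18 without 1 array, and had an adjusted p of 0.838 in the fit without a filter. No setting called an enrichment near C3ar1, with odds ratios of 0.88 to 1.22 without 1 array. The immunoglobulin count, 40 as reported, was 12 with only probes well above background on all 6 arrays and 25 without WT replicate 1. The Lpl value changed from -0.55 to 1.32 with the mean of its probes, where probes disagree. In the deposited log2 table Gpx1 was at 0, against 0.23 in the main setting, and the cause was not tested. Leaving out saturated spots changed nothing because there were none, and a slide term was not run because each slide held 1 genotype. Genes near the floor have only bounds.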

Other observations

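The tests on the proximal tubule share, the clock genes and the immunoglobulin transcripts were chosen after those results were seen. The lists in this and the next paragraph were not called by camera. Of all genes 14.3% were called, against 29.4% of the collecting duct and distal tubule lists and 31.2% of the renin-angiotensin and endothelial lists, in both directions. Among the lists above, the share was 8% for complement, 6.90% for matrix and fibroblast genes and 5.88% for tubular injury. Of 17 collecting duct markers 4 rose and 1 fell (8 and 1 when adjusted over the list alone; camera, adjusted p = 0.096), with the water channel Aqp2 at 0.88 (SE 0.07, adjusted p = 0.00374) and Aqp3 at 0.40. Of 16 genes of the renin-angiotensin system and blood pressure 4 rose and 1 fell (4 and 2 over the list alone, adjusted p = 0.57). The endothelin receptor gene Ednrb rose by 1.05 (SE 0.12, adjusted p = 0.00905), Nos3 by 0.39, and the angiotensin receptor gene Agtr1a fell by 0.32. Of 16 endothelial markers 4 rose and 1 fell (5 and 2 over the list alone, adjusted p = 0.331), with Plvap, Cldn5 and Pecam1 at 0.42, 0.47 and 0.51 and Kdr at -0.53. Of 17 thick ascending limb and distal tubule markers 3 rose and 2 fell (the same over the list alone, adjusted p = 0.357), and of 18 podocyte markers Cd2ap and Wt1 passed by their brightest probes (0.35 and 0.43, the same over the list alone, list adjusted p = 0.0605). A second Wt1 probe stood at -0.02, so no direction is given for Wt1, and 2 other Cd2ap probes stood at 0.01 and 0.10. In the distal tubule list Klhl3 was at least 1.68-fold higher, and Pvalb and Sostdc1 fell by 0.47 and 0.59.

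Heat shock genes (1 of 16 rose, Hspa8 at 0.60, adjusted p = 0.103), interferon-stimulated genes (1 of 25 rose, Ifi44 at 0.67, adjusted p = 0.57) and circadian clock genes (2 of 19 rose and 1 fell, adjusted p = 0.623) were not called. Nor were androgen-dependent genes (1 of 18 rose, Cyp2d9 at 0.71, adjusted p = 0.775), NRF2 and glutathione genes (1 of 26 rose and 1 fell, adjusted p = 0.862) or erythroid genes (1 of 10 rose, Epor at 0.70, adjusted p = 0.858). Neutrophil markers (1 of 9 fell, Ly6g at -0.49, adjusted p = 0.383), adrenal markers (1 of 8 fell, Hsd3b1 at -0.43, adjusted p = 0.752) and adipocyte markers (1 of 7 passed, Lpl, whose probes disagreed in direction, adjusted p = 0.331) were not called either. Of 11 genes that vary between mouse strains, 3 passed at 0.27 to 0.31 by their brightest probes (Nnt, Glo1 and Wdfy1, adjusted p = 0.776). Another Nnt probe was at -0.10, so no direction is given for that gene, and a Glo1 probe was at 0.02 and 2 Wdfy1 probes at 0.03. Adjusted over the list alone, each of these lists had at most 3 higher and 2 lower genes. Of 4 sex-chromosome markers, too few for the list test, Eif2s3y fell by 0.37 (adjusted p = 0.0268).

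The immediate early genes were not called (camera, adjusted p = 0.862; 1 of 23 rose, Gadd45g at 1.09), with 0 passing over the list alone and a test direction of up but a median of -0.26 and a mean of -0.37. Fos and Egr1, chosen after their values were seen, stood at 2.59 and 4.34 in WT replicate 3, against -3.42 and -2.99 (Fos) and -0.90 and -0.79 (Egr1) in WT replicates 1 and 2 and at most -3.09 and -0.72 in C3aR-/- cortex. The mean of the 23 genes was 1.33 in WT replicate 3 and lay between -0.40 and 0.08 on the other 5 arrays. The 8 called lists were called without that array too, when 1444 genes were called. Lpl, the called adipocyte marker, had 6 probes that disagreed. Its brightest probe was at -0.55, 2 others at -0.40 and -0.47, and the remaining 3 at 2.03, 3.59 and 3.74 with adjusted p values of 0.018, 0.00895 and 0.0112 among all probes.

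Of the 10 splits of the 6 arrays only 1, the real one, gave as many as 2931 genes, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. Against artefacts bound to single spots as the whole cause stand the other probes of called genes, of which 865 of 1267 (68.3%, 95% interval 65.6 to 70.8) kept the direction. The interval counts these probes as independent, although they belonged to 859 genes and to the same arrays, so it may be too narrow. The share that kept the direction was 59.5% for genes that were not called and 83.3% (30 of 36) for genes called at least 2-fold. Part of the smaller calls may therefore rest on a single probe. The 8 spike-in controls that were well above background differed between the slides by -0.20 after scaling (C3aR-/- minus WT; exact permutation test, p = 0.1, the smallest possible), without overlap. Before scaling they overlapped and differed by -0.035 (exact permutation test, p = 0.5), so most of that difference came from the 75th percentile, which was 0.16 higher on the C3aR-/- slide. These controls decide nothing about gene-specific effects of labelling, hybridisation or RNA handling, and slide and genotype cannot be told apart.

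By camera, fatty acid oxidation genes were higher and cholesterol synthesis genes lower in C3aR-/- cortex, which could follow from several sources. Neither list was called with an estimated correlation (adjusted p = 0.793 for both), nor cholesterol synthesis with fry (adjusted p = 0.0609). As the whole cause, more proximal tubule tissue would have to move the proximal tubule markers as far. The fatty acid oxidation median lay 0.23 above theirs (95% bootstrap interval 0.04 to 0.49). That interval resamples genes of the same arrays as if they were independent, so it does not measure the spread between arrays. The tubule markers also rose, with a median of 0.19 against 0.42, so such tissue stays open as part of the cause. Another time of day or feeding state at collection stays open. The mean of the clock genes Nr1d1, Nr1d2, Dbp, Tef and Per3 minus that of the opposite arm, Arntl, Npas2, Clock, Nfil3 and Cry1, was 1.81 higher in C3aR-/- cortex, without overlap (exact permutation test, p = 0.1, the smallest possible). Both arms were chosen after the values were seen, so the lack of overlap was in part fixed by that choice. Of clock genes in neither arm, Per2, Usp2, Hlf and Per1 stood at -0.40, -0.18, -0.08 and -0.08, and Wee1 at 0.39. Without the 3 called clock genes Nr1d1, Nr1d2 and Cry1, C3aR-/- replicate 1 at 1.28 overlapped WT replicate 3 at 1.32. The labels used here give no time of collection, and the genotype itself is untested as a source.

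A lower content of plasma cells in C3aR-/- cortex is a candidate explanation of the immunoglobulin result. Lymphoid tissue attached to the WT pieces would bring T cells, but the T cell and NK cell median lay 1.56 above the immunoglobulin median of -1.72. That median had only the 13 transcripts dim on every C3aR-/- array at their bound. Those dim on only some arrays kept their own values, which can widen the difference. The 95% bootstrap interval was 1.35 to 1.71 when only the 16 T cell and NK cell genes were resampled, since the immunoglobulin probes are not independent. It does not measure the spread between arrays either. The list does not hold the natural killer receptor genes Klrb1c (-0.91) and Klrk1 (-0.44), which were called with all 6 arrays (the call of Klrk1 was lost when any 1 array but C3aR-/- replicate 1 was left out), and with both added the difference was 1.54 (1.31 to 1.68). The difference was 1.55 for the 15 of 16 markers at least 2-fold over the floor. A single WT array with many plasma cells is also argued against, since the median, with dim transcripts at their bound, was still -1.61 or lower with each WT array left out. Housing, exposure to microbes and the slide remain open beside the genotype.

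A piece of another strain's DNA kept beside C3ar1 would raise the share of calls there if it changed many genes. The odds ratio was 0.82 with an interval up to 1.20, which leaves a small excess possible. A few changed genes would not show in a share of 257 tested genes, so the test does not decide about them. The called genes Clec2h, Klrb1c, Clec9a and Klrk1 lay close together (mm9, chromosome 6, 128626525 to 129562501), and the cause of their changes was not tested.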
